A study of Homo sapiens with 4 samples.

How the data were processed

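RNA of U87MG, an established human glioma cell line, was measured on 4 Agilent 1-colour whole-genome arrays of design 014850. Per the labels, 2 samples carried a retroviral RNAi construct against AEG-1 (gene symbol MTDH) and 2 carried the empty vector, with RNA taken at passage 5 after infection and selection. The labels number the samples 1 and 2 within each group and do not say whether they came from separate cultures, so the p-values may measure technical spread only. All 4 arrays lay on 1 slide and were read in 1 scan, so slide and scan do not differ between the groups.

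The deposited scanner files hold 1 intensity per spot and array, in the scanner's own intensity units, made with Agilent Feature Extraction 10.5.1.1. The deposited processed signal is a background-subtracted and detrended intensity, not scaled between arrays, and the other deposited columns used (flags of 0 or 1 and a detrending factor) are of other units. The authors' table of values is in log2 units and is centred per probe: the median over the 4 arrays was 0 in all 41093 probes or controls listed (tolerance 1e-06). Differences between arrays in that table correlated with the scanner values across probes with a signal of at least 200 (Pearson r from 0.993 to 0.995 over the arrays, slopes from 0.977 to 1.002), so its direction and log base are those of the scanner values, while its normalization between arrays remains unknown. Its column medians were -0.00187 and 0.0157 in the vector samples and -0.0372 and 0.0253 in the RNAi samples.

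Within a scanner file the columns can be checked against each other, because the processed signal is the background-subtracted signal divided by the detrending factor, and the spot mean is the background-subtracted signal plus the background used. This check was made after the data had been examined. Of 173504 non-control spots, 25931 held a surrogate value, which equalled the processed signal in every case. Among the 147573 others, the processed signal lay within 0.498% of the recomputed signal (tolerance 1%) on all but 44 spots. These 44 spots belong to 6 genes, among them VEGFA, MET, CCND1, MMP2 and MMP9. The deposited values were kept for the principal counts, as had been fixed before the data were examined, and the gene counts, the named genes and the gene lists were also computed with these spots recomputed from the other columns and with these spots left out. The detection counts, the test per probe, the placement tests and a second hypoxia list were not. No single gene whose call depends on the contradicted values is reported as changed, but the principal counts include 2 such genes.

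The base-2 logarithm of the processed signal was taken and each array's 75th percentile over non-control probes was subtracted. Control spots and spots with an outlier mark (95 and 129 on the vector arrays, 112 and 123 on the RNAi arrays) were left out, and spots of the same probe were averaged. A probe counted as well above background on an array if at least a share of 0.5 of its spots did. By this measure 30187 and 28667 of 41000 probes were well above background on the vector arrays (73.7% and 70.0%), and 29881 and 29600 on the RNAi arrays (73.0% and 72.2%). No spot was saturated (0 on each array), and the median coefficient of variation of replicated probes within an array was 4.18% and 3.21% for vector and 3.11% and 2.93% for RNAi. Precision is limited by the number of arrays.

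Probes well above background on both arrays of at least 1 group were kept (29365), and 74 of them with an outlier mark on some array were left out, which left 29291. Gene names came from the reference table of RefSeq genes, by accession for 25398 probes, by symbol for 2510 and by synonym for 788. The other 12304 kept the name in the file. Probe positions are those of the files, on genome build hg18. The brightest kept probe stood for each gene, which gave 21243 genes, 13890 of them with a symbol. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 residual and 2.43 prior degrees of freedom, prior SD 0.0864), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are RNAi over vector. A gene well above background on neither array of a group has only a bound there, and where 1 of 2 arrays measured it, the fitted fold change is given with that number. The bound is given as at least N-fold, the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the probe's own signal.

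Gene lists (30 lists, 642 genes, 565 measured) were fixed before the data were examined and tested with camera in limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and the directional and mixed fry tests were run beside it. With an estimated correlation camera rests on the 2 residual degrees of freedom, so a call lost there need not come from correlation among members. Directional fry asks whether a list's genes move 1 way on balance, and mixed fry whether they move in either direction. Neither compares them with other genes. Fry without further name is the directional test. The genes named are MTDH, the 12 largest rises and 12 largest falls among genes with a symbol past the threshold whose groups did not overlap, and up to 4 passing members, or 2 members with the largest change where none passed, of each list. Genes named outside this rule are said to be so. The alternatives fixed in advance were normexp background correction (offset 50), quantile and median scaling, no filter and a stricter filter on dim probes, the mean of all probes of a gene, a variance trend, the replicate number as a block, the authors' values, and each array left out in turn. For genes and lists that did not pass, a change of sign under an alternative was not counted as a reversal. On data simulated with 21243 genes, the procedure recovered 1 of 67 genes changed 1.5-fold (1.49%), 41 of 67 changed 2-fold (61.2%) and 64 of 66 changed 4-fold (97.0%), with 10 false calls among 116. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading files, tests of placement and drawing.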

Results

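Transcript levels were measured in U87MG glioma cells with stable silencing of AEG-1 (2 arrays) and in the same line with the empty vector (2 arrays). Between 70.0% and 73.7% of the 41000 probes were well above background on each array. The arrays correlated across genes with Pearson's r from 0.994 to 0.998, where genes are not independent replicates. The comparison addresses which transcripts differ between these cells, AEG-1 being a protein linked to invasion and survival of tumour cells. The labels name no RNAi construct against another target. Other effects of the construct, or a difference between the selected populations, thus cannot be told apart from the loss of AEG-1.

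MTDH, the gene of AEG-1, fell 4.03-fold in the RNAi cells. Its probe A_23_P250196 (hg18, chromosome 8, 98806321 to 98806380) gave processed signals of 10944 ± 296 and 10256 ± 207 on the vector arrays and of 2851 ± 74.7 and 2512 ± 45.2 on the RNAi arrays (SD over 9 spots within an array). The log2 fold change was -2.01 with SE 0.0821 (2 arrays per group, limma adjusted p = 0.0158 after Benjamini-Hochberg). MTDH was lower than in both vector arrays on both RNAi arrays. Left out in turn, the arrays gave MTDH values from -2.08 to -1.95, and the adjusted p was 0.0539 without vector replicate 2, 0.168 without RNAi replicate 1 and 0.157 without RNAi replicate 2.

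Among 21243 genes, 47 were higher and 90 lower in the RNAi cells (limma with Benjamini-Hochberg, adjusted p under 0.05). Of these, 21 of the rises and 64 of the falls were at least 2-fold. With the contradicted spots recomputed, 88 genes fell, 62 of them at least 2-fold. The strongest rises included NGFR, the low-affinity neurotrophin receptor, and the neighbouring developmental regulators HOXC8 and HOXC9. The strongest falls included PDE4A, a cyclic AMP phosphodiesterase, the endosomal sorting protein SNX10 and the cytokine TNFSF12. The percentage of passing genes that rose was 34.3% here and 44.8% with median scaling, under which 241 genes passed.

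NGFR (probe A_23_P389897, hg18, chromosome 17, 44946977 to 44947036) rose by a log2 fold change of 2.89 ± 0.112 (SE, 2 arrays per group, limma adjusted p = 0.0141 after Benjamini-Hochberg). HOXC9 rose by 1.96 (adjusted p = 0.0132 in limma) and HOXC8 by 2.18 (adjusted p = 0.0244 in limma), with 2.03 at the other HOXC8 probe. KCTD8, an auxiliary subunit of the GABA-B receptor, rose 2.82-fold, and CSTA, the cysteine protease inhibitor cystatin A, rose by 1.32 on the log2 scale. ARMC2 rose by 1.60, though only 1 of its 2 vector arrays was well above background. The growth factor FGF9 was at least 2.65-fold higher (limma adjusted p = 0.0207), its probe not being well above background in vector cells. The same held for MSR1, a scavenger receptor of macrophages, at least 2.48-fold higher, and for the ADP-ribosyltransferase ART5, at least 2.38-fold higher. ZFPM2, a cofactor of GATA factors, was at least 1.91-fold higher, LDB2, a LIM-domain binding protein, at least 1.31-fold, and DCC, the netrin receptor, at least 1.20-fold.

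SNX10 (probe A_23_P8513, hg18, chromosome 7, 26380261 to 26380320) was at least 6.21-fold lower in the RNAi cells, where it was not well above background (limma adjusted p = 0.00983). PDE4A fell by a log2 fold change of 2.67 ± 0.0672 (SE, 2 arrays per group, limma adjusted p = 0.00983), with 1 of 2 RNAi arrays well above background. TNFSF12, known as TWEAK, fell by 2.15, and CELF2, an RNA-binding regulator of splicing, by 2.03, with a fall by 2.42 at its other probe. RARB, a retinoic acid receptor, fell by 2.39 with 1 of 2 RNAi arrays well above background, and FAIM, an inhibitor of Fas-mediated apoptosis, by 2.24. The neuropeptide NMU fell 4.01-fold, and on the log2 scale the orphan nuclear receptor NR0B1 fell by 1.84 and the secreted peptide FDCSP by 1.73. ARHGAP36 was at least 2.06-fold lower, and TRIM63, a muscle ubiquitin ligase, at least 1.30-fold lower.

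**Figure D1:**
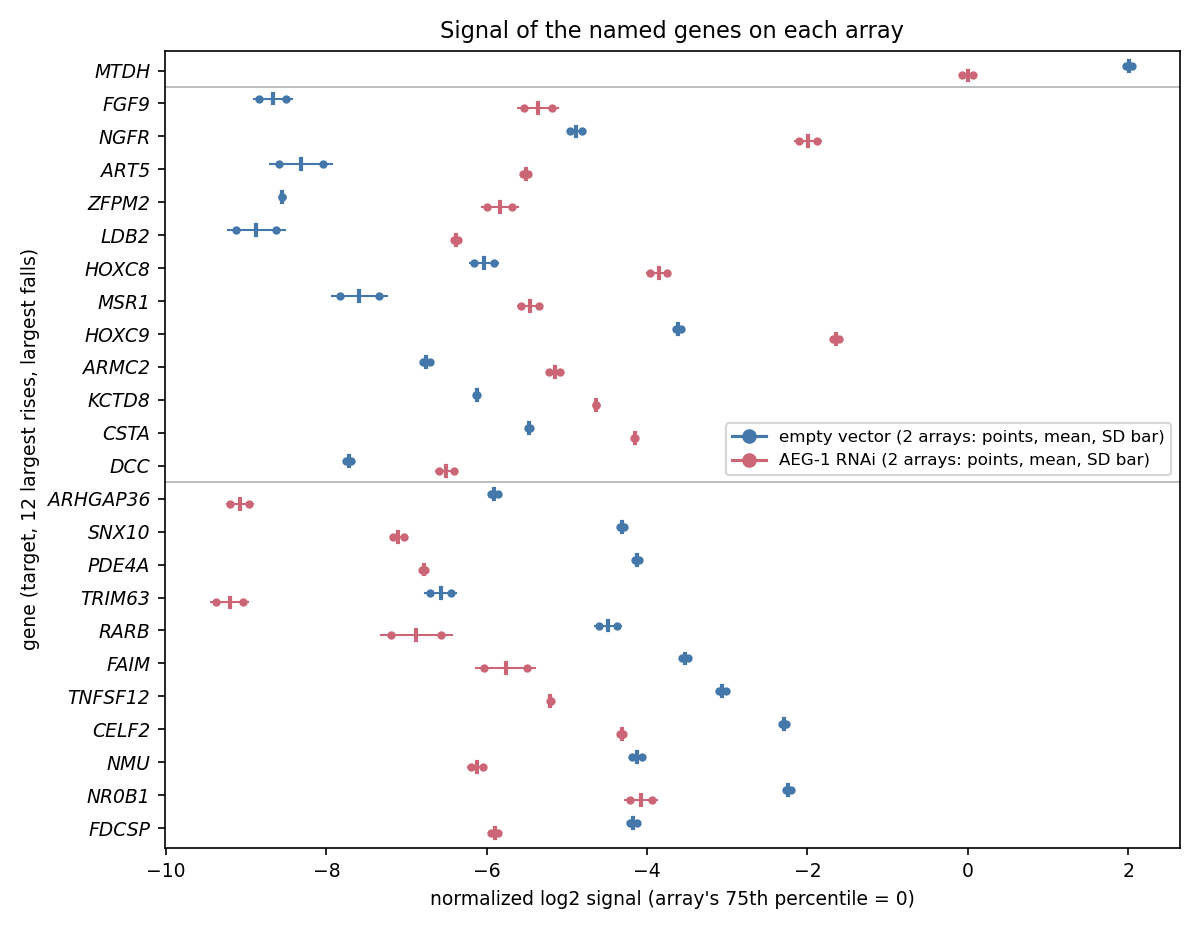
Normalized log2 signal (array's 75th percentile = 0) of MTDH, of the 12 largest rises and of the largest falls on each array, with points for the 2 arrays per group, ticks for the mean and bars for the SD. MTDH fell by 2.01 and NGFR rose by 2.89 on this scale, and a gene not well above background in a group has only a bound there.

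A fit with 1 array left out has a lone array in 1 group and fewer residual degrees of freedom, so a loss of calls does not single out an array. The counts of passing genes were lower in each such fit. They were 80 without vector replicate 1 and 12 without vector replicate 2, and no gene passed in limma without RNAi replicate 1 (0 genes, 2895 at an unadjusted p under 0.05) or without RNAi replicate 2 (0 genes, 2299). With the replicate number as a block, which assumes a pairing the labels do not state, 0 genes passed in limma and 2487 had an unadjusted p under 0.05, against 3511 without the block. The counts were 224 with normexp background correction, 671 with a variance trend and 0 without the filter on dim probes (2842 at an unadjusted p under 0.05). The calls of FGF9, LDB2, DCC, TRIM63 and MAP2 ended with normexp, those of MSR1, DCC and RARB with quantile normalization, that of DCC with a variance trend, those of ARMC2 and RARB with the mean of all probes, and those of LOX and SMAD6 with the replicate numbers crossed as a block. Of the genes measured on 1 of 2 arrays of a group, PDE4A was at -1.19, RARB at -1.01 and ARMC2 at 0.53 on the log2 scale with normexp.

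Few members of the lists on inflammation and matrix passed over all genes. Among 20 measured NF-kB targets, 1 fell, TNFAIP2, an endothelial and myeloid response gene, by a log2 fold change of 1.61 (limma adjusted p = 0.0207), while 19 did not pass. Adjusted over the list alone, 9 passed, 5 of them higher. Counts adjusted over a list alone, here and below, were not adjusted over the 30 lists. Of all 21243 genes 3511 had an unadjusted p under 0.05 in limma, so such counts alone do not mark out a list. Among 26 extracellular matrix genes, LOX, the collagen cross-linking enzyme, rose by 0.68 (limma adjusted p = 0.0469) and 25 did not pass, with 10 passing adjusted over the list alone, 6 of them higher. Among 24 proteases and inhibitors, PLAU, the urokinase plasminogen activator, fell by 0.79 (limma adjusted p = 0.0455), and with the contradicted spots recomputed it was the 1 member that fell. The list's 7 genes passing adjusted over the list alone (recomputed) included 4 higher. In fry the list had an adjusted p of 0.0331 from deposited values and of 0.249 from recomputed ones. Of 10 neuronal markers, MAP2, a microtubule protein of dendrites, rose by 0.98 (limma adjusted p = 0.0374), and 9 did not pass, with the same 1 member passing adjusted over the list alone.

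Genes of glycolysis and the hypoxia response were higher as a group: 27 of 29 measured members were higher in RNAi cells, with a median log2 fold change of 0.13 (camera adjusted p = 1.18e-06). With an estimated correlation the call ended (adjusted p = 0.694), and in the directional fry test the adjusted p was 0.0330. No member passed over all genes (0 of 29), and 8, all higher, passed adjusted over the list alone. They included CA9, a hypoxia-induced carbonic anhydrase, at 1.42, NDRG1 at 0.78 and, chosen after their values were seen, the pyruvate dehydrogenase kinase PDK1 at 0.49 and the collagen prolyl hydroxylase P4HA1 at 0.45. Cholesterol and fatty acid synthesis genes were higher in 19 of 25 (median 0.14, camera adjusted p = 0.00182). This call ended with an estimated correlation (adjusted p = 0.694), in fry (adjusted p = 0.0880) and without vector replicate 1 (adjusted p = 0.0692). None passed over all genes, and 4 passed adjusted over the list alone, among them SCD at 0.59 and, chosen after its value was seen, INSIG1 at 0.58. FOXO targets were higher in 14 of 20 (median 0.12, camera adjusted p = 0.0175). This call too ended with an estimated correlation (adjusted p = 0.694), in fry (adjusted p = 0.249) and without vector replicate 1 (adjusted p = 0.159). None passed over all genes, and 7 passed adjusted over the list alone, 5 of them higher, including TXNIP at 0.68 and PIK3IP1 at 0.48. The number of lists past the threshold was 2 without vector replicate 1, 3 without vector replicate 2, 5 without RNAi replicate 1 and 3 without RNAi replicate 2.

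**Figure D2:**
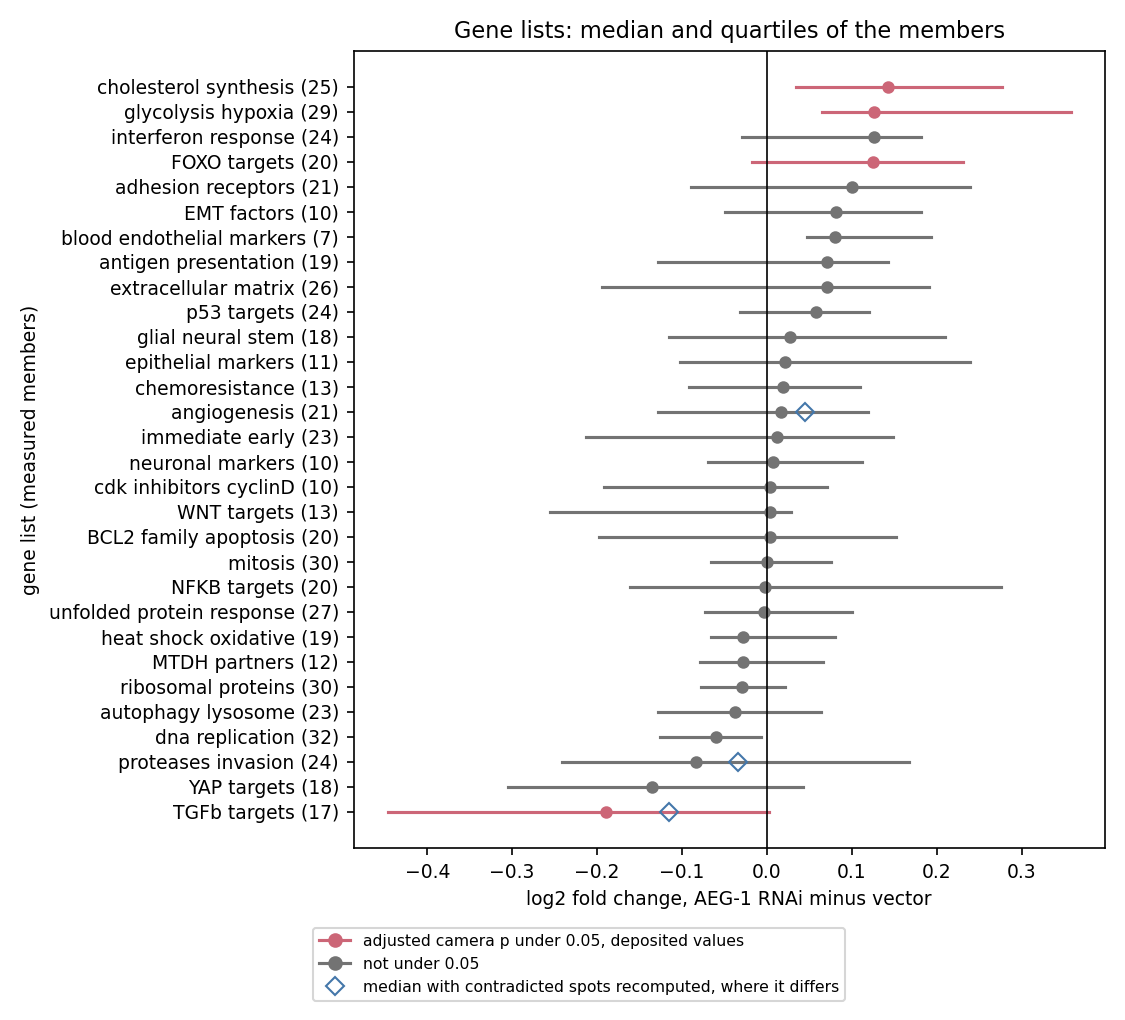
Median (points) and quartiles (bars) of the log2 fold change over the measured members of each of the 30 gene lists, with open diamonds where recomputing the contradicted spots moved the median. The glycolysis and hypoxia list had 27 of 29 members higher, and the TGF-beta list lost its call with recomputed spots.

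TGF-beta targets were lower in 12 of 17 with a median of -0.19 (camera adjusted p = 0.0332) from deposited values, but not past the threshold with the contradicted spots recomputed (median -0.12, adjusted p = 0.123), and with an estimated correlation the adjusted p = 0.694. In fry the adjusted p was 0.0232 from deposited and 0.0319 from recomputed values. SMAD6, an inhibitor of BMP signalling, fell by 0.78 (limma adjusted p = 0.0423), and with recomputed spots it was the 1 member that fell and 7 passed adjusted over the list alone, 2 of them higher. The call also ended without vector replicate 1 (adjusted p = 0.0596), vector replicate 2 (0.0715) or RNAi replicate 2 (0.138).

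In 25 lists no member passed over all genes, and 26 lists did not pass camera, with medians from -0.14 to 0.13. Interferon-induced genes (24 measured, median 0.13, adjusted p = 0.0685) had ISG20 at 0.58 and OAS3 at -0.56, and 4 passed adjusted over the list alone, 3 of them higher. The interferon list passed camera with normexp (adjusted p = 0.0293), without the filter on dim probes (0.0278), with the mean of all probes (0.0306) and with a variance trend (0.0316). YAP targets (18, median -0.14, adjusted p = 0.124) had TGFB2 at -0.45 and AXL at -0.40, and 7 passed adjusted over the list alone, 2 of them higher. The YAP list passed in fry (adjusted p = 0.0232, or 0.0319 with recomputed spots) and in camera with a variance trend (adjusted p = 0.0371). DNA replication genes (32, median -0.06, adjusted p = 0.127) were lower in 24, with CCNE2 at -0.57, and passed without vector replicate 1 (adjusted p = 0.0178), without RNAi replicate 1 (0.0334) and with a variance trend (0.0371). Adhesion receptors (21, median 0.10) had L1CAM at least 1.19-fold higher in RNAi cells (not well above background in vector cells, not past the threshold) and ITGA11 at -0.73, and astroglial and stem cell markers (18, median 0.03) had NES at -0.91 and SOX4 at -0.81. Factors of epithelial-mesenchymal transition (10, median 0.08) had SNAI1 at -0.53 and FN1 at 0.41. Adjusted over the list alone, 4 adhesion receptors, 3 glial or stem cell markers and 2 transition factors passed. The adhesion list passed camera without the filter on dim probes (adjusted p = 0.0491). Immediate early genes (23, median 0.01) had EGR1 at 0.52 and EGR2 at 0.46, and 4 passed adjusted over the list alone, 3 of them higher. The BCL2 family (20, median 0.003) had HRK at 0.48 and 1 member passing adjusted over the list alone, and p53 targets (24, median 0.06) had BTG2 at 0.35 and none passing.

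Mitotic genes (30, median 0.0002), ribosomal proteins (30, median -0.03), the unfolded protein response (27, median -0.004) and heat shock and oxidative stress genes (19, median -0.03) did not pass camera. Nor did antigen presentation (19, median 0.07), autophagy and lysosome genes (23, median -0.04), drug resistance genes (13, median 0.02), genes of AEG-1 binding proteins (12, median -0.03), Wnt targets (13, median 0.004), angiogenic factors (21, median 0.02, or 0.04 with recomputed spots) or CDK inhibitors and D cyclins (10, median 0.004). Epithelial markers (11, median 0.02) and blood and endothelial markers (7, median 0.08), genes of other cell types, did not pass either. Adjusted over the list alone, 1 autophagy and lysosome gene and 1 epithelial marker passed, and no other gene of these lists did with recomputed spots. In mixed fry, from deposited values, most of the 30 lists had an adjusted p under 0.05, so it singles out few of them. Its adjusted p was 0.00425 for mitotic genes and 0.00106 for the unfolded protein response. For ribosomal proteins it was 0.496, and for heat shock and oxidative stress genes 0.206.

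Deposited processed signals of 6 genes contradicted the other columns of the same spots, and none of these genes is reported as changed. MET, MMP2 and MMP9 are named for these spots, after their values were seen. The spots numbered 42 on the RNAi arrays, all below the signal recomputed from the other columns, and 2 on the vector arrays, both above it. The same 20 positions were contradicted on both RNAi arrays. The deposited signal was 5.79% to 34.4% of the recomputed signal on 16 spots of VEGFA, 11.5% to 24.6% on 8 of MET, 32.9% to 36.3% on 6 of MMP2 and 54.0% to 74.8% on 6 of CCND1. On the 2 vector spots, of MMP9, it was 373% and 428%. The log2 fold change of MET, a receptor tyrosine kinase, was -1.14 from deposited values (limma adjusted p = 0.0469) and -0.12 from recomputed ones (adjusted p = 0.493). CCND1 gave -0.37 and -0.20, MMP2 gave -0.19 and 0.26, and MMP9 gave -0.25 and -0.03, with no adjusted p under the threshold in either. For VEGFA, the angiogenic growth factor, probe A_23_P81805 had mean signals of 3021 and 2917 on the vector arrays, and on the RNAi arrays 1328 and 1567 as deposited but 3588 and 3587 recomputed. In the test per probe, from deposited values, VEGFA probes A_23_P70398 and A_23_P81805 were at -2.22 and -2.13 (limma adjusted p = 0.0115 and 0.0147). These calls rest on contradicted spots. VEGFA probes A_24_P12401 and A_24_P179400, at -0.72 and 0.39, did not pass. With the spots recomputed, A_23_P70398 was at 0.257 (limma adjusted p = 0.397). Leaving the spots out gave -0.12 for MET. With either treatment 135 genes passed, 47 higher and 88 lower, and 2 genes were lost, MET among them.

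**Figure D3:**
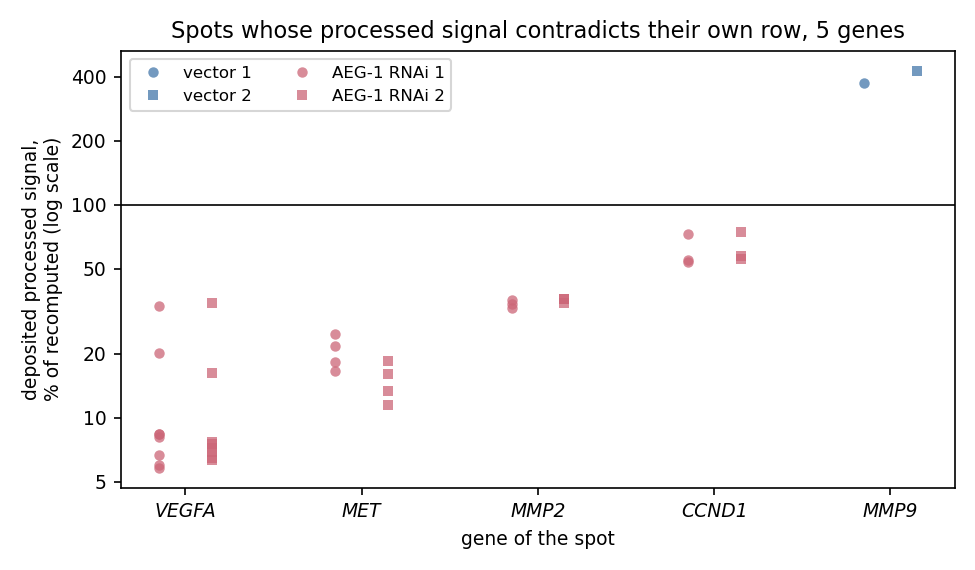
Deposited processed signal as a percentage of the signal recomputed from the other columns of the same spot (log axis, line at 100), for the contradicted spots of 5 of the 6 genes, by gene and array. The RNAi spots shown lie below the line, at 5.79% to 74.8%, and the 2 vector spots of MMP9 lie above it.

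In 142 genes every probe was not well above background in 1 group while a probe was in the other, 97 measured only in RNAi cells and 45 only in vector cells, and 18 of the 142 passed the limma test. They include FGF9, ART5, MSR1, ZFPM2, LDB2 and DCC, higher in RNAi cells, and SNX10, ARHGAP36 and TRIM63, higher in vector cells. With an array left out, where only 1 array of that group has to be well above background, this count was 1014 without vector replicate 1, 562 without vector replicate 2, 382 without RNAi replicate 1 and 342 without RNAi replicate 2. It was 233 with the scanner's other detection mark.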

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

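The crossed pairing of replicate numbers, the recomputing or leaving out of the contradicted spots, the test per probe, the detection counts without an array and fry with the contradicted spots recomputed were chosen after seeing the data. The principal counts, from deposited values, were 137 genes past the threshold, 47 higher and 90 lower, 85 of them at least 2-fold. They became 224 genes with normexp (83 higher, 141 lower, 32 at least 2-fold), 241 with median scaling (108 higher), 72 higher with quantile normalization (167 in all) and 671 with a variance trend (287 higher, 384 lower). No gene passed in limma without the filter on dim probes (0 genes, 0 higher, 0 lower, 2842 at an unadjusted p under 0.05) or with the replicate block (0 genes, 2487). Leaving out each array gave 0 to 80 genes, 0 to 16 higher, 0 to 64 lower and 0 to 80 at least 2-fold. With an array left out 1 group has a lone array, assumed to vary like the other group, and fewer residual degrees of freedom. Otherwise the cause was not tested. The crossed pairing as a block gave 149 genes (49 higher, 100 lower), against a correlation of same-numbered deviations of -0.123. The authors' values gave 140, the mean of all probes 126, the stricter filter 172 and the test per probe 144. The last count, from deposited values, includes VEGFA and MET through contradicted spots.

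MTDH stayed at -2.01 without the filter (adjusted p = 0.211) and with the block (adjusted p = 0.149), and ranged from -2.08 to -1.95 with an array left out (adjusted p from 0.0328 to 0.168). Lists past the threshold numbered 4, 7 with a variance trend, 2 to 5 with an array left out, 0 with an estimated correlation in camera (raw p 0.0249 for the smallest, adjusted p = 0.694) and 3 with the contradicted spots recomputed or left out. Detection differences numbered 142, 233 with the other detection mark and 342 to 1014 with an array left out, where only 1 array of a group has to be well above background. Over the named genes and alternatives, 1031 values kept their side of the threshold, 38 came to pass and 165 no longer passed. Over the lists these counts were 543, 12 and 15. A gene or list that had not passed could only stay so or come to pass, so the kept values include many that never passed. Without the filter on dim probes 29 named genes no longer passed, as did 29 with the replicate block, and no named gene passed in either. In the 4 lists past the threshold the estimated correlation ran from -0.0538 to 0.0131, near or below the preset 0.01. Their calls thus ended in that test through the 2 residual degrees of freedom, not through correlation among members. Fry passed 4 lists, or 3 with the contradicted spots recomputed. Among the named genes and the lists, compared at gene level, no passing result changed direction under any alternative run. A block for slide or scan was not run, because all 4 arrays share 1 slide and 1 scan. Signal over background limits the genes given as bounds: with normexp, FGF9, LDB2, DCC and TRIM63 did not pass.

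The contradicted spots change which genes pass. Recomputed from the other columns or left out, they gave 135 genes (47 higher, 88 lower, 83 at least 2-fold), with 2 lost, MET among them, and 0 gained. The cause of the contradiction was not tested.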

Other observations

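The tests of neighbouring genes, of regional shifts and of scaling, the round-step count of the contradicted spots, and the split of the 234 genes by whether they have another probe were chosen only after the results were seen.

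Genes named in this paragraph were chosen after their values were seen. The alarm cytokine IL33 fell by a log2 fold change of 1.35, IL18, an inflammasome cytokine, by 1.21, and TLR4, the receptor of bacterial lipopolysaccharide, by 1.12. The chemokine CCL3 rose by 1.03. The hyaluronan synthases parted, with HAS1 falling by 1.13 and HAS2 rising by 0.74. EDNRB, an endothelin receptor, fell by 1.16, and HSD11B1, which activates glucocorticoids, rose 2.15-fold. Probes of MEG3, a long noncoding RNA, disagreed at -3.51 and 0.11.

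The difference between the recomputed signal, rounded to the precision of the file, and the deposited signal was a multiple of 100 on 20 of the 30 contradicted spots with a recomputed signal under 10000. Unrelated values would give this on 10% of spots with a signal of 1000 or more and on 1% of dimmer ones. The difference was 1000 on all 6 spots of MMP2. The spot mean and the spot median lay further apart than the pixel SD on 9 of the contradicted spots and on 0 of the others. No explanation was tested.

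Between the vector arrays 234 genes differed at least 2-fold, against 102 between the RNAi arrays. Spots of the 234 genes had another such spot within 3 array positions in 55.6% of cases, above the 27.4% of the 95th percentile of 1000 random draws (median 21.8%), so local spot defects may contribute. The RNAi arrays had 39.2% against a random median of 9.80% and a 95th percentile of 16.7%. Such spots clustered in both pairs, so clustering cannot tell why the vector pair had more of these genes. In the 19 genes with another probe, the other probes moved by a median of 0.0037 in the aligned direction (95% interval -0.0707 to 0.241), against 1.30 at the chosen probes and the 0.5 that a real difference in RNA was predicted to need, which argues against it for these genes as a set, though 4 moved by at least 0.5. The 215 genes without another probe were not tested, so a real difference between the samples stays open there.

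Entries without a gene symbol were left out of the count of neighbours. Among them, LOC644215 and AK123083 had log2 fold changes of -2.02 and -2.09 in the test per probe, where MTDH had -2.01. Their probes start at 98809164 and 98809847 on chromosome 8, near that of MTDH at 98806321. Whether they read transcripts separate from MTDH was not tested. The 106 called genes with a symbol and a position held 4 same-direction pairs within 1 Mb. These were HOXC9 with HOXC8, CCL3 with CCL3L3, HCLS1 with CSTA and MEST with PODXL. Random sets gave a median of 4 and a 95th percentile of 9 (permutation p = 0.646, one-sided), which is consistent with chance placement. The 128 other genes around the pairs had an aligned median of 0.0162 (95% interval -0.0197 to 0.0521), a test chosen after the pair count came out at chance. This argues against a copy-number change common to the 4 regions. The regions were pooled, so the median cannot decide about any 1 of them. The chromosome median furthest from 0 was -0.0635, on chromosome 9, which argues against gain or loss of a whole chromosome in all cells. Small shifts were present: 35.6% of 884 genes were higher on chromosome 9 and 36.7% of 1033 on chromosome 5. On chromosome 18, 62.0% of 316 genes were higher. Medians of this size cannot decide about a gain or loss in a part of the cells.

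The higher glycolysis and hypoxia genes may reflect a stronger hypoxia response in the RNAi samples. A second list of 34 hypoxia-induced genes, written after the first result but before its own values were seen, had a median log2 fold change of 0.127, with 24 of 31 measured genes higher (camera p = 1.07e-05, and p = 0.126 with an estimated correlation). Intensity-dependent scaling is argued against, since the first list's median exceeded that of all genes by at least 0.138 under quantile and normexp settings. Cell density and oxygen in the dishes are not stated, so a culture difference stays open beside an effect of AEG-1.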
